A study of Mus musculus with 2 samples.

How the data were processed

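Spleen cells of wild-type and Ecm1 knockout C57BL/6 mice, described as female and 6 weeks old, were depleted of red cells, and CD4 cells were isolated magnetically with an anti-CD4 antibody, per the labels' protocols. The series' design text calls the starting cells naive, and the isolation protocol names CD4 only. The cells were cultured for 4 days with plate-bound anti-CD3 (3 µg/ml), anti-CD28 (2 µg/ml), IL-4 (10 ng/ml, the unit being read from a garbled label), anti-IFN-γ (10 µg/ml) and anti-IL-12 (10 µg/ml). From 3 µg of total RNA, biotin-labelled cRNA was made with the one-cycle Affymetrix assay, per the labels' protocols. Each group had 1 array, and the number of animals behind an array is not given in the sources used here.

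The deposited values are linear probe-set signal intensities, 1 per probe set and array, for 45101 probe sets of an Affymetrix mouse array. The summarisation software, its version and its settings are not given in the sources used here. The values show a global scaling, since the mean over the central 96% of probe sets was 500.004 on both arrays, while other quantiles differed (75th percentile 423.4 in the knockout and 456.2 in wild type), so the arrays were not quantile normalised. Such a scaling fixes the mean signal of an array, so a rise in some abundant transcripts lowers the values of the others. No detection calls were used here. The number of arrays limits the precision.

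Probe sets were named through the platform annotation given for this work. Of the probe sets, 34945 had 1 gene symbol, 932 had several and 9160 had none, and 64 were control probe sets. Gene identifiers of 34741 of the probe sets with 1 symbol were found in the RefSeq gene table, and 0 symbols needed updating. Only probe sets with 1 symbol were used to name genes, which gave 18193 genes, 9010 of them with several probe sets. Of the 20 focus genes 18 were named by it, and the others were not analysed here. The files give no genome build, and no coordinates are reported.

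Signals below the median of their array (65.5 in the knockout, 69.2 in wild type) were treated as at the floor. Signals were taken to log2 and the difference, knockout minus wild type, was centred on its median over the 20834 probe sets at or above the floor on both arrays, which was -0.10. A gene's value is that of its brightest probe set by mean log2 signal over the arrays. A gene below the floor on 1 array has only a bound, its signal on the other array against the floor, and a gene below it on both has no fold. With 1 array per group no test between groups was run. Genes at least 2-fold apart were counted, and the spread between probe sets of the same gene, as the SD of the difference of the 2 brightest divided by the square root of 2, was the only internal measure of error.

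Before the data were examined, 34 gene lists (21 of processes and T cell states and 13 of markers of other cell types), the focus genes, the 2-fold threshold, the floor, the rule for named genes and the alternative settings were fixed. Each list's median used members at or above the floor on at least 1 array, with signals below the floor set to it. It was placed by percentile among 10000 random lists of the same size matched in 20 bins of mean expression, as a description of these arrays. Lists with fewer than 3 such members were given as counts, which applied to 2 lists. The text names the focus genes, the 12 genes each way with the largest difference among genes at or above the floor on both arrays whose other measured probe sets go the same way and whose symbol is not a clone name, the 5 genes each way with the largest bound, and up to 4 members of each list with the largest difference. Genes named outside this rule, such as Xist, Jchain, Hspa5, Zap70, Cd3e, Fcgr3, Hlx, Mki67, Alb and the genes of the lists added later, were chosen after their values were seen. Of 154 genes the rule names, 7 had measured probe sets of opposite direction: Cd8a, Cdc45, Igk, Ndufb8, Rpl7, Rps9 and Stat5b.

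The procedure was tested on simulated data with the real signals of 10428 genes and noise of the measured technical SD. Changes were planted only in genes well above the floor. The noise was independent between probe sets, with the same SD at every signal level. The planted 2-fold change equalled the calling threshold, so the rates below follow largely from these settings. The procedure called 47.8% of genes changed 2-fold, 98.5% of those changed 4-fold and 100% of those changed 8-fold, and 50 of 10228 unchanged genes (0.489%). Changes in genes near the floor, and animal, culture and array error, were thus not covered by these rates. Of 100 lists without a shift, 4 lay outside the central 95% of random lists, and 20 of 20 lists shifted by 0.5 did. These lists were drawn at random from genes with independent noise, so they give no error rate for lists of genes expressed together. Alternatives were no centring, quantile normalization, an intensity-dependent loess with span 0.3, no floor, a floor at the 70th percentile, the mean over a gene's probe sets, leaving out probe sets whose name ends in _x_at or _s_at, thresholds of 1.5-fold and 3-fold, and 10 matching bins. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.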

Results

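Transcript levels were measured in T helper 2 (Th2) cells, the CD4 T cells that make interleukin-4 (IL-4) and related cytokines, from mice lacking Ecm1 and from wild-type mice. Ecm1 encodes a secreted glycoprotein of the extracellular matrix. The comparison asks which transcripts differ when Th2 cells lack it, among them those for leaving lymphoid organs. The series held 2 arrays, 1 for the Ecm1 knockout and 1 for wild type, each hybridised with RNA from splenic CD4 cells cultured for 4 days under Th2 conditions. Titles and source names call both samples Th2 cells, whereas the sample descriptions name liver, so hepatocyte genes were also examined. There were no replicates, so no difference carries a test, an SD or a p-value across replicates, and each describes these 2 arrays only. The tests, SDs and intervals given below run over genes or probe sets. Their log2 signals correlated at r = 0.940 across 20834 probe sets at or above the floor on both arrays. In 4657 genes with a second measured probe set, the log2 differences of the 2 brightest correlated at r = 0.70 (Spearman 0.65, across genes, which are not independent replicates). Their technical SD was 0.36 on the log2 scale, which leaves out animal, culture and array error.

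Ecm1 itself was among the brighter transcripts of the wild-type Th2 cells and was below the floor in the knockout. Its single probe set read 29114.7 on the wild-type array and 19.3 on the knockout array, where the floor was 65.5. Set against that floor, the log2 difference (knockout minus wild type, used throughout) was -8.69 or lower. The position of the probe set relative to the deleted part of the gene is not given in the sources used here.

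Of 10144 genes at or above the floor on both arrays, 725 were at least 2-fold higher on the knockout array and 451 at least 2-fold lower, and 8968 lay within 2-fold. The 2-fold genes thus split 61.6% higher after centring, against 49.0% in the signals as deposited, where 587 were higher and 611 lower. A further 1121 genes reached the floor on 1 array only, of which 105 were at least 2-fold higher and 50 at least 2-fold lower by their bound. The largest positive differences were in Atp1b1, a sodium pump subunit (4.46), Eaf2 (3.95), Chil3, a chitinase-like protein of IL-4-exposed macrophages (3.84), the amino acid transporter Slc7a5 (3.70) and the plasma cell proteoglycan Sdc1 (3.70). They were followed by the lysozymes Lyz2 (3.45) and Lyz1 (3.39), the secretory-cell factor Bhlha15 (3.35), the chemokine Pf4 (3.32), arginase Arg1 (3.25), Fkbp11 (3.11) and the antibody light-chain segment Igkv14-111 (3.09). The largest negative differences were in the granzyme Gzmc (-4.13), Ifit1bl1 (-3.13), Selenbp1 (-2.74), Itga7 (-2.67), Ipcef1 (-2.64), the T cell adaptor Trat1 (-2.64) and the costimulatory receptor Cd27 (-2.53). Below these came Tdrp (-2.50), the chemokine receptor Ccr2 (-2.44), Pde2a (-2.37), Klf2 (-2.33) and Cyria (-2.33). With their probe sets averaged, the knockout signals of Cyria and Ipcef1 fell below the floor, which left bounds of -0.05 and -0.58. Without probe sets whose name ends in _x_at or _s_at, Fkbp11 had a bound of 0.93, its wild-type signal (54.6) lying below the floor. Lysozymes, granzymes and antibody segments belong to families of near-identical genes whose probe sets can share signal, so their single-gene values are uncertain.

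Among genes below the floor on 1 array, the bounds were highest for the Y-linked Eif2s3y (5.10), the cell cycle inhibitor Cdkn2a (3.61), Gpm6a (3.24), Fads3 (3.11) and Cpeb3 (3.04). They were lowest for Ecm1, Gzmd (-4.42), Gzme (-2.87), Slfn5 (-2.52) and Tgfb3 (-2.46). With its probe sets averaged, which takes in signals below the floor, Slfn5 had a bound of -0.55. With the floor at the 70th percentile, the bounds of Cpeb3, Fads3, Gzme, Slfn5 and Tgfb3 were under 2-fold. Eif2s3y read 2214.4 on the knockout array and 25.0 on the wild-type array. The 3 probe sets of Xist, the transcript of the inactive X chromosome, were at 41.6%, 51.6% and 47.4% of wild type on the knockout array, while the labels describe female mice. Xist was singled out after its values were seen.

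**Figure D1:**
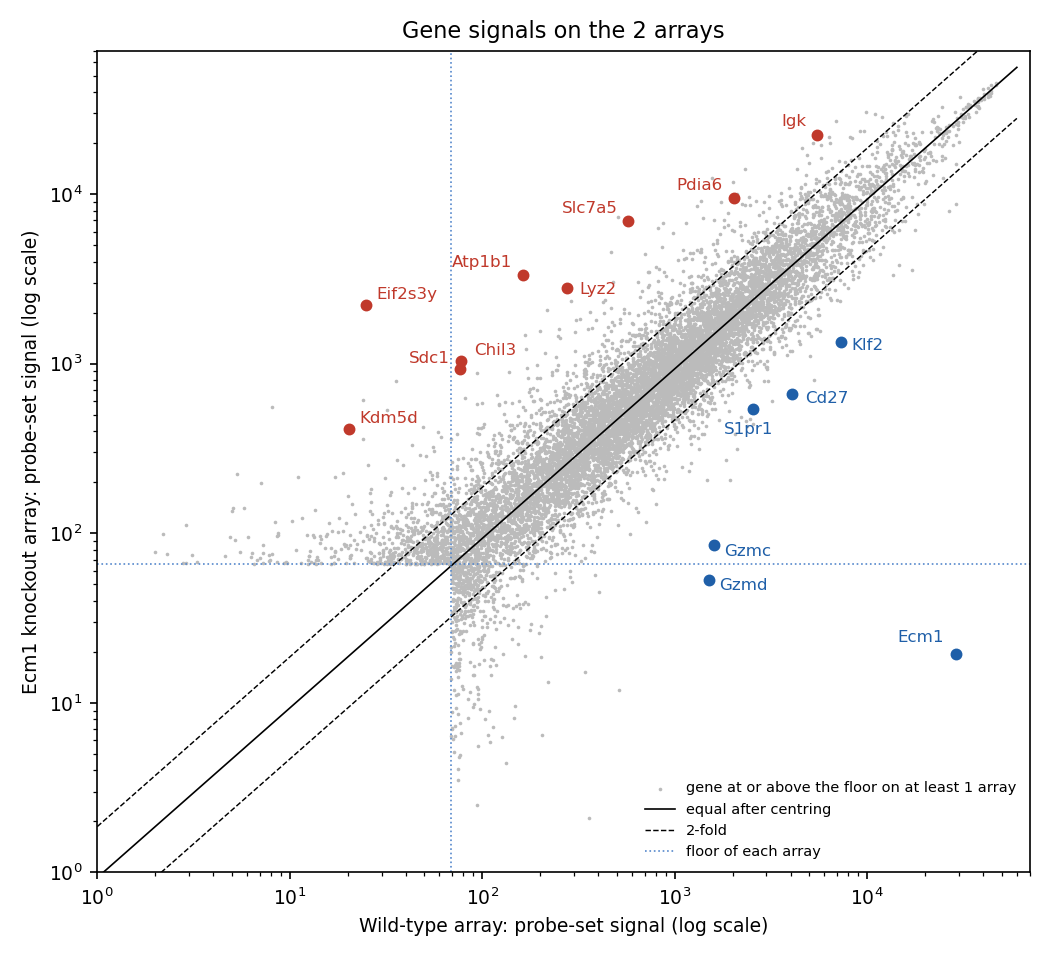
Probe-set signal of each gene on the wild-type array (x axis, log scale) and on the Ecm1 knockout array (y axis, log scale), for genes at or above the floor on at least 1 array, with named genes coloured. Most points lie between the dashed 2-fold lines, and Ecm1 lies far to the lower right at 29114.7 in wild type and 19.3 in the knockout.

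Genes for leaving and homing to lymphoid organs were lower as a group in the knockout. S1pr1, the sphingosine-1-phosphate receptor that T cells use to leave lymph nodes, read 540.7 against 2553.1 in wild type, 4.40-fold lower after centring. Klf2, a transcription factor that drives S1pr1, read 1350.2 against 7282.1, 5.02-fold lower after centring. Cd69, whose product pulls the S1pr1 receptor off the cell surface, went the other way, with 1480.2 against 615.7. Of the 23 measured members of the egress and homing list, 8 were at least 2-fold lower, 1 (Cd69) at least 2-fold higher and 14 neither. The list median was -0.69, below all 10000 random lists, which were matched on expression and not on cell type. On the same arrays the T cell receptor signalling list had a median of -0.76, so the egress list as a whole was not lower than that list. The integrins Itga6 (-1.52) and Itgb7 (-1.45) were among the lower members, and the lymph node homing receptor Ccr7 was at -0.99. Without the members it shares with other lists, the egress median was -0.36, at percentile 0.24 of its random lists.

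Transcripts of naive and resting T cells were lower as a group. All 23 measured members of that list lay below 0, 9 of them at least 2-fold lower and none at least 2-fold higher, and the median of -0.89 was below all 10000 random lists. Cd27 (-2.53), the repressor Bach2 (-1.69) and the IL-7 receptor Il7r (-1.43, with -2.59 in its other probe set) stood beside S1pr1 and Klf2. T cell receptor signalling genes were also lower as a group, with 6 of 24 members at least 2-fold lower, none at least 2-fold higher and 18 neither (median -0.76, below all 10000 random lists). These included Cd4 (-1.59), the kinase gene Prkcq (-1.37), the receptor chain Cd247 (-1.29) and Dgka (-1.21), while Cd3e was at -0.77 and Zap70 at -0.98. S1pr1 lay -1.37 from that list's median and Klf2 -1.57, and none of the 24 genes on the list was as low as either. Trat1, a T cell receptor adaptor that is not on the list, was lower than both at -2.64, with -3.11 in its other probe set.

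Most Th2 genes lay within 2-fold, and as a group they were slightly lower. Il4 read 923.1 in the knockout and 1233.0 in wild type (-0.31), and Gata3, the Th2 master regulator, 5958.6 and 7423.4 (-0.21, and -0.42 after quantile normalization). Il10 was at 0.15, and at -0.05 after quantile normalization. Il13 read 240.6 against 69.6 (1.89), its wild-type signal lying at the floor of 69.2, and Il5 read 68.3, just above the floor, in the knockout and 26.1, below the floor, in wild type. Of 21 measured Th2 genes, 1 (Il13) was at least 2-fold higher, 1 (Ecm1) at least 2-fold lower and 19 neither. The median was -0.33, at percentile 0.315 of the random lists, on arrays where the T cell receptor signalling list had a median of -0.76.

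For IL-2 signalling through STAT5, Il2ra was at 0.74, Il2rb at -0.15 (-0.32 after quantile normalization) and Stat5a at -0.48, or -0.95 as the mean of its 2 probe sets. The 2 probe sets of Stat5b disagreed, at -1.06 and 0.17. Of the 25 members of that list, 2 were at least 2-fold higher, among them the cytokine Lif (1.37), 3 at least 2-fold lower, among them Socs3 (-1.16), and 20 neither. The median was -0.21, at percentile 0.96.

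Several Th1 and cytotoxic transcripts were lower. Tbx21, the Th1 master regulator, read 504.7 against 1489.8 (-1.46), the chemokine Ccl5 was at -1.97 and the IL-18 receptor Il18r1 at -1.49, whereas the transcription factor Hlx (214.7 against 11.0, a bound of 1.74) and the cytokines Tnf (1.36) and Lta (1.06) were higher. With the floor at the 70th percentile, the wild-type signal of Tnf fell below it, which left a bound of 0.01. Lta was at 0.96 without centring and just under 2-fold after quantile normalization. Ifng was below the floor on both arrays. The Th1 list had 6 of 18 members at least 2-fold lower, 3 at least 2-fold higher and 9 neither (median -0.29, percentile 1.32, and percentile 3.56 with no floor, inside the central 95% of random lists). CD8 T cell markers had a median of -0.98, below all 10000 random lists, with 5 of 10 at least 2-fold lower and none at least 2-fold higher. Natural killer markers had a median of -0.67 (percentile 0.04), with 4 of 9 at least 2-fold lower, 1 at least 2-fold higher and 4 neither. The lists overlap, and Klrd1 (-2.09), Nkg7 (-1.77) and Gzma (-1.64) lead both, with only a bound of -0.78 for Klrd1 at the higher floor. The 4 probe sets of Cd8a measured on both arrays ran from -1.19 to 0.40. Interferon-induced genes were lower as a group, with 7 of 27 at least 2-fold lower, 1 at least 2-fold higher and 19 neither (median -0.77, below all 10000 random lists). The lower ones included Usp18 (-1.63, and a bound of -0.48 at the higher floor), Iigp1 (-1.22) and Ifit2 (-1.16).

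**Figure D2:**
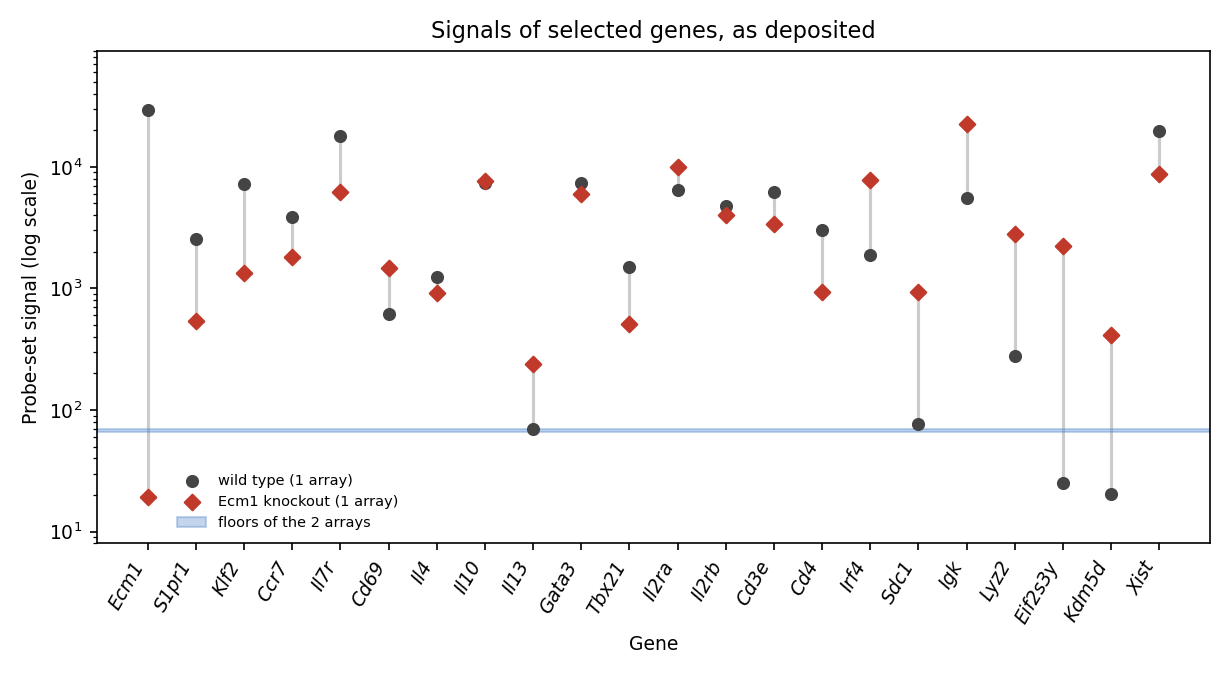
Probe-set signals as deposited (y axis, log scale) of selected genes (x axis), with dark circles for the wild-type array and red diamonds for the Ecm1 knockout array, 1 array each, and the band marking the floors of the arrays. S1pr1 reads 2553.1 in wild type and 540.7 in the knockout, while Il4 and Gata3 lie close together.

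Genes of the unfolded protein response, which expands protein folding in the endoplasmic reticulum, were higher in the knockout. Of 24 members, 17 were at least 2-fold higher, none at least 2-fold lower and 7 neither, and the median of 1.46 was above all 10000 random lists. Creld2 (2.80), Sdf2l1 (2.35), the disulphide isomerase Pdia6 (2.33) and asparagine synthetase Asns (2.23) led the list, and the abundant chaperone Hspa5 read 23615.0 against 9657.9. Markers of antibody-secreting plasma cells were higher on the same array, with 6 of 8 at least 2-fold higher and 2 neither (median 1.92, above all 10000 random lists). Sdc1 (3.70), Derl3 (2.31), Irf4 (2.14) and the antibody heavy chain Igha (2.04) led them, and 3 of the 8 are also on other lists. The wild-type signal of Sdc1 (76.9) lay near the floor, and its other measured probe sets were at 2.45 and 0.79. The other probe set of Irf4 was at 0.95, and those of Igha at 2.22 and 2.56. B cell markers had a median of 0.85, above all 10000 random lists, with 5 of 14 at least 2-fold higher and 9 neither, led by Blnk (2.46), the light chain Igk (2.13), Cd79b (1.28) and Blk (1.08, and 0.98 without centring). B-lineage transcripts were abundant on both arrays although the cells had been isolated with an anti-CD4 antibody: Cd79b read 10153.2 in the knockout and 4493.9 in wild type, and the antibody joining chain Jchain, singled out after its values were seen, 26366.0 and 13593.4. Jchain counts among the 6 plasma cell markers past 2-fold (1.06), but was at 0.96 without centring, 0.92 after quantile normalization and 0.95 after loess. Antibody probe sets did not all move alike, since 1 of the 4 for Igk was at -1.09.

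Macrophage markers were higher as a group in the knockout. Of 21 macrophage and monocyte markers, 9 were at least 2-fold higher, 2 at least 2-fold lower and 10 neither (median 0.72, above all 10000 random lists). Lyz2 read 2796.2 against 275.5 and the Fc receptor Fcgr2b 3484.8 against 876.5, while the chemokine receptor Ccr2 (-2.44) and another Fc receptor, Fcgr3 (960.1 against 2969.6, -1.53), were lower. Dendritic cell markers, mostly antigen-presentation genes that B cells share, had a median of 0.80 (percentile 99.9), with none of 9 past 2-fold, and included H2-Ab1 (0.99) and Cd74 (0.87). Neutrophil markers had a median of 0.67 over 5 genes (percentile 98.7, and 81.6 with no floor). Among them Mmp8 was at 1.72 (a bound of 0.03 at the higher floor) and Il1b at 1.02 (0.92 without centring).

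Cell division genes were higher as a group. All 34 members of the cell cycle list lay above 0 after centring, 8 of them at least 2-fold higher, and the median of 0.82 was above all 10000 random lists. The replication genes Cdc6 (2.00), Ccne2 (1.73) and Mcm5 (1.39) were highest besides Cdc45, whose brighter probe set was at 2.05 and other at -0.47, and the proliferation marker Mki67 was at 0.82. Genes of oxidative phosphorylation had a median of 0.46 (percentile 99.5), with 1 of 23, Ndufa4 (1.37), at least 2-fold higher. Glycolysis genes had a median of -0.38 (percentile 0.05), with 2 of 19 at least 2-fold lower, the glucose transporter Slc2a3 (-2.17) and Aldoc (-1.25), and 17 neither. Of 27 T cell activation genes, 6 were at least 2-fold higher, none at least 2-fold lower and 21 neither, among them Slc7a5 (3.70), Irf4 (2.14) and Slc3a2 (1.53), and Irf4 is also on the plasma cell list. That list's median was 0.33 (percentile 97.9) and 0.11 (percentile 64.1) without members of other lists.

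**Figure D3:**
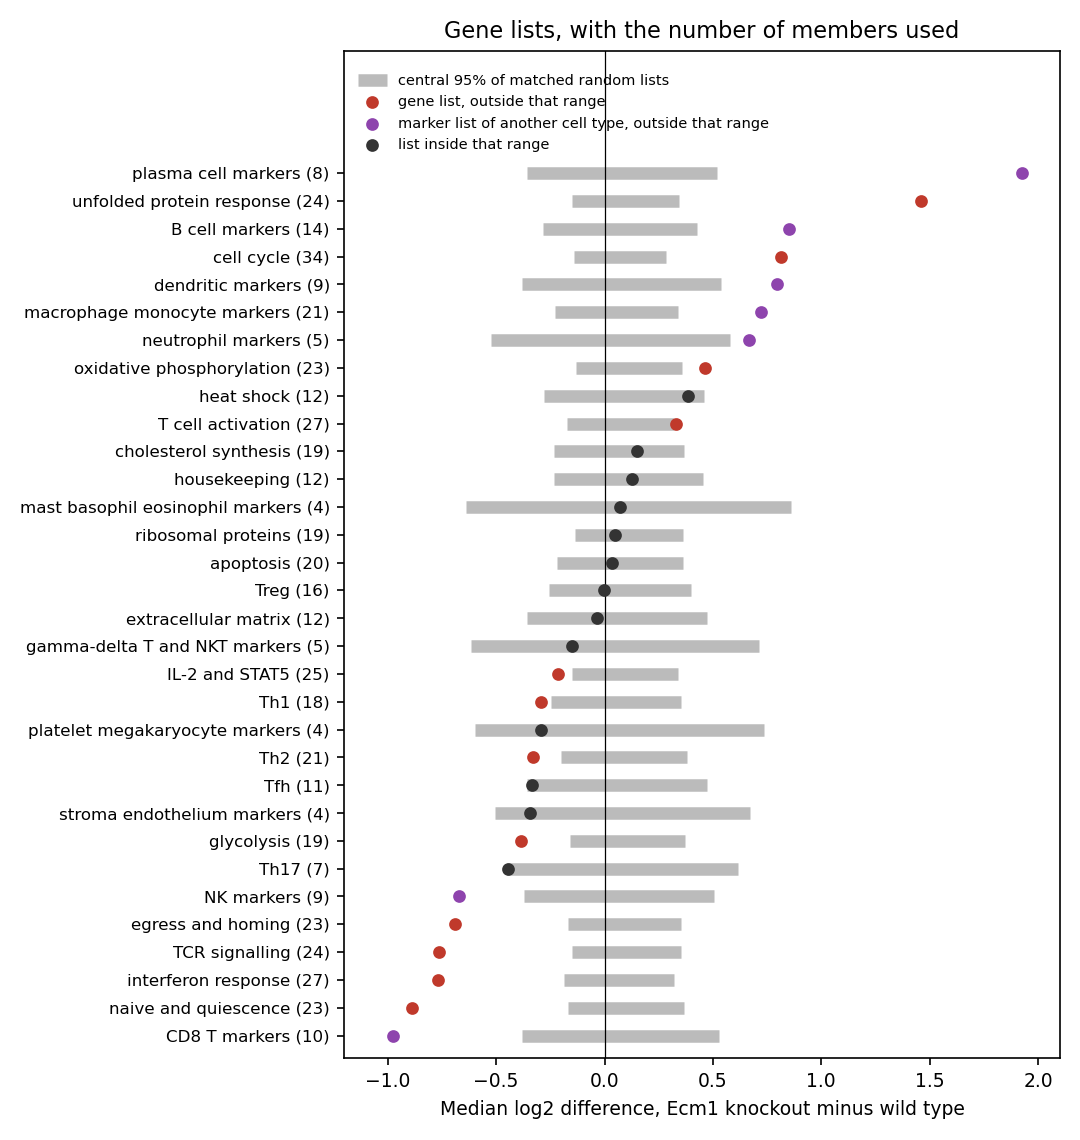
Median log2 difference, Ecm1 knockout minus wild type (x axis), of each gene list (y axis, measured members in brackets), with grey bars for the central 95% of 10000 matched random lists. Plasma cell markers (1.92) and the unfolded protein response (1.46) lie highest, and CD8 T cell markers (-0.98) and naive T cell genes (-0.89) lowest.

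The remaining lists stayed inside the central 95% of their random lists. Regulatory T cell genes had a median of 0.00 with none of 16 past 2-fold, although Ctla4 was at -0.99 and Foxp3 was near the floor at 68.3 and 93.2. T follicular helper genes were at -0.33, with Pou2af1 (1.87) and Cxcr5 (1.65), which B cells also express, above and Sh2d1a (-1.43) and Il21 (-1.19) below. Th17 genes were at -0.44, heat shock genes at 0.39, cholesterol synthesis genes at 0.15, housekeeping genes at 0.13, ribosomal protein genes at 0.05, apoptosis genes at 0.03 and extracellular matrix genes at -0.03. The ribosomal protein, apoptosis and extracellular matrix medians change sign under other scalings or summaries. Stroma and endothelium markers were at -0.34, platelet markers at -0.29, γδ T and NKT markers at -0.15 and mast cell, basophil and eosinophil markers at 0.07, or -0.03 without centring. Of 22 hepatocyte genes on the array, 2 reached the floor on either array, and albumin (Alb) read 24.1 and 4.8. Erythroid markers likewise had 2 such members, and neither was past 2-fold.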

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

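The probe sets without a gene name, which enter the centring and the correlation between arrays but no gene or list value of the report, leaned towards lower signal in the knockout. Of 2883 at or above the floor on both arrays, 321 were at least 2-fold lower and 126 at least 2-fold higher. Among 17951 named probe sets the split was opposite, with 841 lower and 1296 higher. The median of the unnamed probe sets was -0.18 on the log2 scale, against 0.03 for the named ones. No test was run on these values.

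The poly-A spike-in transcripts, added to RNA before labelling and outside every comparison of the report, had a median log2 difference of -0.33 over 22 probe sets, 20 of them lower in the knockout. The hybridisation controls, added after labelling, had a median of 0.15 over 18 probe sets, with an SD of 0.0979 between them. The ratio of 3' to 5' signal was 1.15 in the knockout and 1.17 in wild type for Actb, and 0.836 and 0.851 for Gapdh.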

How the results depend on the processing

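No paired analysis was possible because each group had 1 array. Of 19 lists outside the central 95% of random lists, 16 stayed outside in the same direction under every alternative run. Th1 lost its place with no floor, neutrophil markers with no floor and without _x_at and _s_at probe sets, and T cell activation in 6 of 9 alternatives. The Th17 list moved outside in 3 alternatives, and the heat shock and stroma lists in 1 each. Of 1622 alternative values of 233 results, 131 moved beyond their spread or by over 1.5 times, and no called direction reversed. Leaving out members shared with other lists was chosen after seeing the data. Unless an alternative's construction shows it (fewer genes, another threshold, another bound), the cause was not tested. Signal near the floor limits what weak transcripts can show. With the higher floor 27 named genes had no value, with the mean of probe sets 7 and without _x_at and _s_at probe sets 6.

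With quantile normalization, medians moved to -0.90 for egress, -0.91 for T cell receptor signalling, 0.65 for cell cycle, -0.56 for glycolysis and 0.31 for oxidative phosphorylation. With loess they were -0.82 for egress, 0.70 for cell cycle and -0.52 for glycolysis. With no floor, 2818 genes were higher and 2316 lower, Ecm1 was at -10.47, and medians were -1.07 for natural killer, 1.27 for macrophage and 0.37 for neutrophil markers, while the correlation between probe sets of a gene dropped to 0.165. At the 70th percentile floor, 416 genes were higher and 285 lower, the Ecm1 bound was -6.62, medians were -0.46 for Th1, 1.66 for plasma cell and 0.94 for macrophage lists, and that correlation was 0.768. With the mean of probe sets, medians were -0.12 for Th17, 0.70 for cell cycle, 1.25 for the unfolded protein response, 0.17 for extracellular matrix, 0.18 for heat shock and 1.55 for plasma cell genes. Without _x_at and _s_at probe sets, stroma markers were at -0.85. At 1.5-fold 1852 genes were higher and 1382 lower, and at 3-fold 224 and 91. Without shared members, egress was at -0.36 and T cell activation at 0.11.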

Other observations

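All tests and added gene lists in this part were chosen after the values were seen, and the lists hold genes seen among the largest differences, so they are not independent evidence. Genes that import and make amino acids and charge transfer RNAs, many of them targets of the stress factor ATF4, were higher in the knockout. Of 38, 24 were at least 2-fold higher, 1 at least 2-fold lower and 13 neither (median 1.22). Among them were Slc7a5 at 3.70, the arginine transporter Slc7a3 at 2.55 and Shmt2 at 1.94. The cysteine-making enzyme Cth was at 2.65, with a bound just under 2-fold when the floor was at the 70th percentile. The machinery that moves proteins into and out of the endoplasmic reticulum was higher too. Of 43 such genes 18 were at least 2-fold higher and none at least 2-fold lower (median 0.88), among them the cargo receptor Lman1 (2.68), Ssr2 (2.07) and the glycosylation subunits Rpn1 (1.87) and Rpn2 (1.89). Both groups stood on the array where plasma cell markers had a median of 1.92 and antibody genes outside the fixed lists 2.13.

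A list of macrophage genes, some induced by IL-4 and others not particular to it, had a median of 1.98 over 17 measured members, 10 of them at least 2-fold higher and 7 neither. Chil3 (3.84), Arg1 (3.25), Clec4n (2.79), the elastase Mmp12 (2.77) and the chemokine Cxcl3 (2.72, and a bound of 0.97 with the floor at the 70th percentile) were highest. The IL-4-induced Ccl24 was at 0.30 and Ccl22 near the floor at 71.0 and 76.5, and Retnla, Ccl17, Mgl2, Clec10a and Chil4 were below the floor on both arrays. Granzyme genes went the other way, with 5 of 7 at least 2-fold lower and 2 neither (median -2.36), and Gzma read 8692.4 against 29033.8, while Gzmb was at -0.34 with 14331.3 against 19512.5. That median is the bound of Gzmg, set by the floor. With the floor at the 70th percentile, the bounds were -0.29 for Gzmg and -0.80 for Gzme, both under 2-fold. Probe sets of these paralogs can share signal.

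S1pr1 and Klf2 were lower in a culture whose T cell receptor genes were also lower. A lower share of T cells stays open. S1pr1, the nearer of both, lay -1.37 from the T cell receptor signalling median and below every member of that list. A shift the size of that median would thus leave part of both differences over. The T cell gene Trat1 (-2.64) was lower still, but it was chosen after it was seen among the largest differences. The comparison with Trat1 therefore cannot decide the question. A general loss of naive transcripts stays open too. The naive list without egress genes lay only -0.0408 from the T cell receptor list (95% bootstrap interval over genes -0.45 to 0.19), against -1.37 for S1pr1. The list as a whole was thus not lower by as much as S1pr1. Its member Cd27 (-2.53) was lower than S1pr1 and Klf2, but that condition was set after Cd27 was seen among the largest differences and cannot decide. Loss of Ecm1 in the T cells may also account for the pattern, and with 1 array per group genotype cannot be told apart from any other difference between the cultures.

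Antibody-secreting cell genes were higher on the knockout array, and in isolated CD4 cells B-lineage RNA may come from cells the column retained. The B-lineage lists did not rise alike on these arrays. Plasma cell markers lay 1.26 above B cell markers after shared genes were left out (95% bootstrap interval over genes 0.13 to 2.92, from 5 plasma cell genes). The interval resamples genes, which are not independent replicates, and leaves out culture and array error. A lower share of T cells that raises every other type alike therefore cannot be excluded by it. More antibody-secreting cells in the knockout sample stay open: 13 antibody genes outside the fixed lists had a median of 2.13, at percentile 100 of matched random lists, but the set was made after antibody genes were seen among the largest differences and so tests nothing. Ighm, on the fixed B cell list, read 37288.9 and 30437.8 in its brightest probe set (0.40), while its other measured probe sets ran from -0.09 to 6.42. An effect of Ecm1 loss on these cells stays open and was not tested.

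Some Y-linked transcripts were present in the knockout sample although the labels describe female mice. RNA from male animals in the knockout sample is a candidate explanation, since 3 Y-linked genes reached the floor in the knockout alone and all 3 Xist probe sets were lower. These genes were Eif2s3y, Kdm5d (410.0 against 20.3, and a bound of 0.48 with the floor at the 70th percentile) and Uty (104.8 against 44.5, and 352.9 against 10.6 in another probe set). Sry (96.3 against 120.4) and Orly (72.0 against 77.8) were not higher, but both lay near the floors of 65.5 and 69.2. The 3 bright probe sets of Xist were lower by a log2 difference of -0.95 or more negative (SD 0.156 between them, which leaves out array error). Xist was picked because it was lower, so this is no separate test. Background on the knockout array, which would add signal, would leave these probe sets at or above wild type and so does not account for them. For the Y-linked genes it was tested in 4 forms by one-sided Fisher's exact tests, the last 2 added after the earlier results were seen: with Eif2s3y, crossing the wild-type floor gave p = 0.0162 and reaching 2-fold over it p = 0.00383, while without Eif2s3y, which prompted the tests, crossing gave p = 0.0848 (2 of 6 against 636 of 7560 others), short of 0.05, and reaching 2-fold in any probe set p = 0.00177 (2 of 5 against 100 of 7531 others), so background is argued against with the caution that the deciding form was the last one tried. Xist still read 8715.3 in its brightest probe set, against 19739.9 in wild type, a mixture of sexes was not tested, and sex may thus differ between the samples along with genotype.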
